A study of Mus musculus with 18 samples.

How the data were processed

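The series holds 18 samples: 12 RNA libraries from 12 mice and 6 antibody samples made from the same cells as the oxazolone RNA libraries, whose counts stand in the same 6 matrices. The 4 groups of 3 mice were imiquimod, its vehicle control, oxazolone challenge and its solvent control, and the labels give each mouse its own sample. The ears of the imiquimod experiment were digested with Liberase TL and sequenced with the version 2 kit of 10x Genomics, and those of the oxazolone experiment with collagenase XI and the version 3 kit, in both cases for 90 min, per the labels' protocols. The 2 experiments also differ in age, so every test of their difference is confounded with kit, enzyme and age.

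The deposited values are whole UMI counts per gene (and per antibody) and cell barcode, not normalised. Per the submitters' processing notes, Cell Ranger 3.1.0, Seurat 3.1.2 and R 3.6.1 and the builds mm10 and GRCh38 were used; which step each served is not given in the sources used here. The oxazolone matrices hold mouse and human genes side by side. The lowest UMI total of a deposited barcode was 500 to 502 in each library. The number of deposited barcodes ran from 1728 to 8123 per library, and 0 matrices belonged to no sample. Gene symbols were those of the matrices (31053 mouse genes), and coordinates came from a RefSeq gene table of GRCm38.p6, the assembly behind mm10, in which 121 of the 122 named genes were found by symbol.

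From the deposited counts, barcodes were kept with at least 300 mouse genes detected, at most 10% mitochondrial UMIs and at least 90% of UMIs on mouse genes. Barcodes with at most 10% on mouse genes were taken as human cells, and those between as mixed. Scrublet, as in scanpy, was run per library with an expected doublet rate of 0.06 and marked 0 to 0.1% of the oxazolone libraries and 0.1 to 1.06% of the imiquimod libraries, so doublet calling did not work in most of them; an alternative left out the 6% of cells with the highest score in each. Cells were scaled to 10000 counts, log-transformed and clustered per experiment on 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.5, with lymphoid cells and phagocytes each clustered again, which gave 48 and 55 clusters. Clusters were named from marker lists of 32 cell types by the highest mean marker score of at least 0.5, with at least 3 markers each detected in a share of 0.1 of the cells. A cluster whose cycling score was highest was called cycling. Clusters stayed unnamed if their 10 leading genes held more markers of another type, if another type of the same lineage reached 0.8 of the best score, if they were deeper than their library's median and a type of another lineage reached 0.5 of it and a score of 0.5, or if they were shallow without a leading marker of their own type. These rules were not part of the plan: they were set once clusters had been seen and were adjusted after looking at which clusters they left unnamed, among them a cluster of Arg1-expressing macrophages. Only the final version was carried into the tests reported here. Other versions of the rules are not among the alternatives. The unnamed cells made up 14.1% ± 1.1 of imiquimod and 5.69% ± 1.45 of control cells, and 1.29% ± 0.15 of challenged and 5.27% ± 0.36 of their control cells (SD, n = 3). Monocyte and macrophage clusters were joined into 1 class, which was not planned either, and the class of cycling cells mixes lineages.

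Counts were summed per mouse and class for every class with at least 20 cells in each library (9 classes after imiquimod, 11 after oxazolone, 8 in both). They were tested with edgeR's quasi-likelihood test (robust fit, TMM, filterByExpr) with Benjamini-Hochberg adjustment within a class; a gene was called at an adjusted p under 0.05. The difference between the responses was tested in 1 fit of all 12 libraries. Class shares were tested with edgeR on cell numbers with all kept cells as library size, beside a two-sided exact permutation test. Antibody counts were summed in the same way and tested with edgeR with TMM over the antibodies. Genes called the same way in at least 3 classes were counted without a p, since classes come from the same mice. Lists of at least 5 measured members were tested with fry (limma) on voom values, adjusted over all list-by-class tests of an experiment, and again with camera with an estimated correlation. Fry asks whether the members of a list changed, and camera whether they changed more than the other genes of the class. A list past fry alone is therefore not shown to change beyond the other genes. The words "with an estimated correlation" stand for camera below. The 20 lists were the type 17 axis, the type 2 axis, type 1 and cytotoxic genes, interferon-stimulated genes, NF-kB targets and inflammatory cytokines, monocyte-attracting chemokines, alarmins and antimicrobial genes, MHC class II presentation, MHC class I presentation, regulatory and checkpoint genes, cell cycle, glycolysis and hypoxia, tissue macrophage and repair genes, eicosanoid and leukotriene genes, skin homing and residence genes, dissociation stress, mitochondrial transcripts, and transcripts of keratinocytes, fibroblasts and red cells that mark free RNA. CPM values use the same TMM library sizes.

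Named genes followed a rule. In each class it took the 3 higher and 2 lower genes of largest absolute log2 change with an adjusted p under 0.05, a mean of at least 50 CPM and no overlap between treated and control mice, which chance gives for 10% of genes with 3 against 3. Haemoglobin, mitochondrial, ribosomal protein, sex-linked and predicted genes and markers of other classes were left out there. It added up to 3 members by smallest adjusted p of each list with at least 3 called members or past fry, 12 fixed genes (Il17a, Il17f, Il22, Il4, Il13, Il10, Ifng, Il1b, Tnf, S100a8, S100a9 and Foxp3), the 10 genes called in the most classes, the 3 genes of smallest p per direction for the difference between responses and every called antibody. The text prints a part of them, the first ones by the rule, and a few genes that the rule takes are not reported here. Markers, lists, this rule for genes, the tests and all other settings were fixed, except the rules on unnamed clusters, the joining of monocytes with macrophages and what was added below, before the data were examined.

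The alternatives were RLE scaling, no filter on low counts, DESeq2, the replicate number as a block, leaving out each library in turn, a mitochondrial limit of 20%, doublets kept, Leiden resolution 0.8, TMM over classes or immune classes alone for shares, camera, centred log-ratios with limma or total counts for antibodies, and 2 or 4 classes for shared genes. Others were added after seeing the data: leaving out the cells of highest doublet score, subtraction of free RNA, cells of matched depth, changes relative to the human cells and leaving out cells above 10 times the library's median antibody total. Free RNA was taken from mouse UMIs in human barcodes and made up 4.26 to 6.88% of the kept UMIs of the oxazolone libraries. Il22, Il17a and Il17f were also counted per cell of the imiquimod mice. The ratio of Il22 to Il17a in cells at or above the median dermal γδ T cell of the same mouse was compared with 10000 draws of as many such γδ T cells (0.5 added to each sum), a test chosen after the result was seen. For each named gene outside cycling cells, the part that transcripts of another class can hold was bounded, also after the results were seen: the lowest ratio, class over source, among at least 2 markers of the source at 200 CPM or more was multiplied by the gene's CPM in the source and set against its CPM in the class, in the group where the gene is higher. Sampling of sparse markers was not allowed for, so the bound is approximate.

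The tests were run on simulated counts drawn from the real means, library sizes and dispersions. Of genes changed by a log2 value of 1 and of 2, 75% and 98.9% were called in CD4 T cells after imiquimod (4645 genes), 66.3% and 95.5% in monocytes or macrophages (8309 genes) and 80.4% and 98.0% in ILC2 (6666 genes). For oxazolone these were 73.1% and 98.9% in CD4 T cells (3142 genes), 90.5% and 99.0% in monocytes or macrophages (9779 genes) and 27.1% and 72.2% in ILC2 (6501 genes), and for the difference between responses in ILC2 22.9% and 67.0% (7331 genes). Between 0.0475 and 0.224% of unchanged genes were called. Of genes changed in mouse cells alone by 1, 40 of 197 were called relative to the human cells in ILC2, and 0 of 189 shifted alike in both species (5811 genes). For antibodies changed by 2 in ILC2, 3 of 6 were called. In ILC2 most changes of 1 were therefore missed after oxazolone and for the difference between responses, and no smaller change was simulated.

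Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and version 1.17.8 of data.table, with the seed 1.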

Results

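Immune and other cells from the ear skin of 12 male C57BL/6J mice were profiled by droplet single-cell RNA sequencing, 1 library per mouse, in 4 groups of 3 mice. In the first experiment 9-week-old mice received 5% imiquimod cream (IMQ), an agonist of Toll-like receptor 7 that is used to provoke psoriasis-like skin inflammation, or a vehicle cream (IMQ-C) for 7 days. In the second experiment 10-week-old mice were sensitised on the back with 3% oxazolone, a contact allergen, and 9 days later the ears received 3 challenges with 0.5% oxazolone (OXA) or with the alcohol solvent alone (OXA-C). The ears were taken 24 h after the last treatment. The libraries held between 9478012 and 18276856 unique molecular identifier (UMI) counts on mouse genes in the imiquimod experiment and between 11596663 and 26950654 in the oxazolone experiment. After filtering, 16928 and 32843 mouse cells were kept, from 1617 to 6998 per library. The median UMI count per kept cell was 4049 to 5385 in IMQ, 2757 to 3392 in IMQ-C, 1818.5 to 2368 in OXA and 3127 to 4267 in OXA-C, so depth differed between treated and control mice, in opposite directions in the 2 experiments. The oxazolone libraries also held 42 antibody tags measured on the same cells, and 5162 barcodes of human cells.

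The first question was which cell classes gained or lost share. After imiquimod, monocytes or macrophages made up 22.5% ± 3.6 of the kept cells against 3.49% ± 0.92 in controls (SD, n = 3 each). Neutrophils rose from 0.245% ± 0.171 to 1.69% ± 0.21 and natural killer (NK) cells from 0.604% ± 0.173 to 3.75% ± 1.72. The neutrophil share leaves out cluster 40, which stayed unnamed with scores of 1.858 for neutrophils and 1.392 for monocytes. That cluster held 211 treated and 2 control cells, beside 117 and 22 in the neutrophil class. Dendritic epidermal T cells, the γδ T cells resident in mouse epidermis, fell from 41.5% ± 3.2 to 13.5% ± 2.9. Basophils, migratory dendritic cells (DC), fibroblasts, blood endothelial cells and Schwann cells also rose, and mast cells, keratinocytes, conventional type 2 DC (cDC2) and cycling cells also fell, so that 13 of 19 classes changed (edgeR, adjusted p under 0.05). Dermal γδ T cells held 11.7% ± 2.4 after imiquimod and 9.44% ± 0.45 in controls and were not called, nor were CD4 T cells, regulatory T cells (Treg), group 2 innate lymphoid cells (ILC2), conventional type 1 DC (cDC1) and Langerhans cells. The smallest p that a two-sided exact permutation test can reach with 3 against 3 mice is 0.1, and 12 of the 13 changes stood at it, with cDC2 at 0.2. The cDC2 change of -0.65 on the log2 scale became 0.04 when cells with up to 20% mitochondrial UMIs were admitted and 1.37 at Leiden resolution 0.8. It lost its call without IMQ-C 1, IMQ-C 3 or IMQ 2, at -0.44, -0.65 and -0.47. Without 1 of 3 libraries (IMQ-C 3, IMQ 1 or IMQ 2) the Schwann cell change was not called, with changes of 0.93, 0.97 and 1.34. That of cycling cells was not called without IMQ-C 1, IMQ-C 3, IMQ 1, IMQ 2 or IMQ 3, at -0.53, -0.60, -0.62, -0.62 and -0.60.

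After the oxazolone challenge, monocytes or macrophages held 56.7% ± 4.3 of the cells against 13.6% ± 1.3 (SD, n = 3 each). Basophils rose from 0.168% ± 0.065 to 6.11% ± 0.27, neutrophils from 0.307% ± 0.090 to 7.16% ± 0.43 and CD8 T cells from 0.100% ± 0.037 to 3.16% ± 0.72. Plasmacytoid DC, migratory DC, NK cells, Treg and CD4 T cells rose too. The classes resident in skin fell: dendritic epidermal T cells by 3.61, ILC2 by 3.59, fibroblasts by 3.33, dermal γδ T cells by 3.30 and Langerhans cells by 2.78 on the log2 scale. Mast cells fell too. Keratinocytes fell by 6.21. Blood endothelial cells, cycling cells, cDC2 and cDC1 fell as well, and 20 of 21 classes were called (edgeR), B cells being the exception. The CD4 T cell change of 0.57 (exact permutation p = 0.3) lost its call without OXA-C 2, OXA-C 3, OXA 2 or OXA 3, at 0.34, 0.49, 0.57 and 0.33, and the cDC1 change without OXA 2, at -0.52. The plasmacytoid DC change of 4.09, which rests on 41 cells, became -2.68 at Leiden resolution 0.8. Shares sum to the whole, so the rise of 1 class lowers the others.

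**Figure D1:**
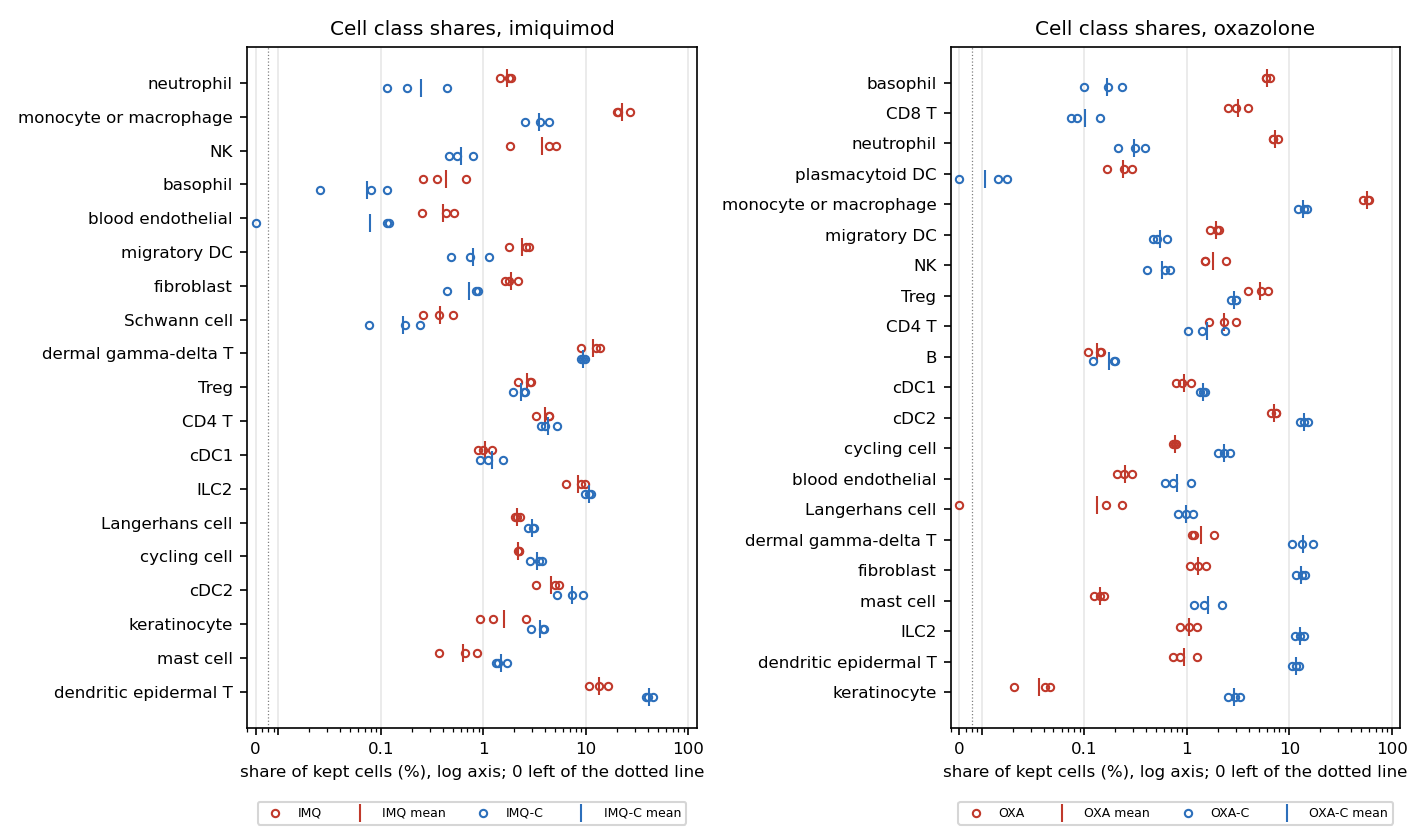
Share of kept cells (percent, log axis) of each cell class in each of 3 mice per group, circles, with the group mean as a bar, for the imiquimod experiment on the left and the oxazolone experiment on the right. Monocytes or macrophages lie at 22.5% after imiquimod against 3.49% and at 56.7% after oxazolone against 13.6%, and dendritic epidermal T cells lie lower in the treated mice of both.

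Within cell classes, the second question was which genes imiquimod changed. In dermal γδ T cells, a source of interleukin-17 in mouse skin, transcripts of type 17 cytokines rose. Il17a (ENSMUSG00000025929, a protein-coding gene on chromosome 1, 20730905 to 20734496, GRCm38.p6), encoding interleukin-17A, rose by 3.80 ± 0.45 (log2 ± SE, adjusted p = 0.00612) from 564 ± 233 to 7834 ± 1997 CPM, the count scaled to the library total (SD, n = 3). Il17a was not called with the replicate number as a block (adjusted p = 0.069). Its neighbour Il17f (chromosome 1, 20777146 to 20785274) rose by 2.88 ± 0.38 from 1719 ± 760 to 12628 ± 193 CPM. Il22 (chromosome 10, 118204584 to 118210047), a cytokine that acts on keratinocytes, stood at 24645 ± 3458 CPM against 2488 ± 3459, a change of 3.31 ± 1.34 that was not called (adjusted p = 0.175). Without the library IMQ-C 2 that change was 5.64 (adjusted p = 0.000899), and DESeq2 called it (adjusted p = 0.0266). Of 15 measured members of the list of type 17 genes, 8 rose in these cells, and 8 when adjusted over the list alone. Among them were Ccr6, the receptor for the chemokine Ccl20, by 1.30 ± 0.12, Stat3, which transmits interleukin-23 and interleukin-6 signals, by 0.99 ± 0.10, and Il1b by 1.34 ± 0.17. The list passed the fry test (adjusted p = 0.00635; adjusted p = 0.153 with an estimated correlation). The inflammatory cytokine Tnf fell by 0.89 ± 0.14, Amd2 fell by 1.66 ± 0.14, and Cebpb, a transcription factor, fell by 1.85 ± 0.31, a call that ended without IMQ-C 2, IMQ-C 3 or IMQ 1 (adjusted p = 0.0558, 0.0581 and 0.0601). Il13 stood at 297 ± 207 CPM against 28.8 ± 25.3 and was not called (adjusted p = 0.0703), while DESeq2 and the 20% mitochondrial limit called it (adjusted p = 0.00718 and 0.0364). Of 17 dissociation stress genes, 10 fell and 2 rose in this class (11 and 2 adjusted over the list alone). By the markers of monocytes or macrophages in treated dermal γδ T cells, up to 55.4% of the Il1b counts there may be transcripts of those cells. Cluster 6 held 606 of the 865 treated cells of this class and 42 of the 927 control cells, most of which lay in clusters 5 (598) and 10 (287). Where treated and control cells of a class lie in different clusters, a change of its cells is not told from a change in its mix of cells.

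**Figure D2:**
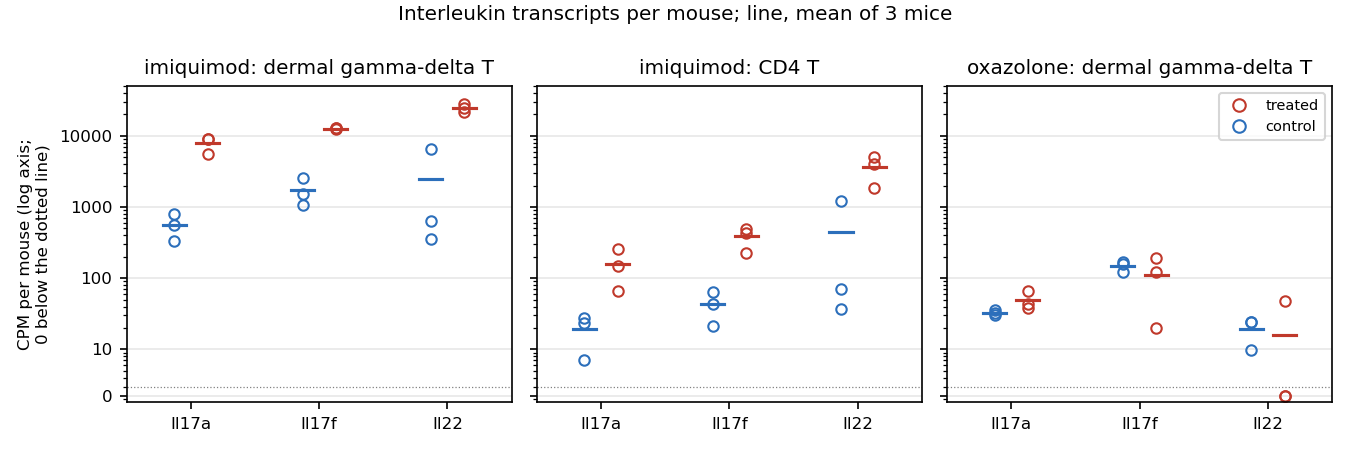
Il17a, Il17f and Il22 in CPM (log axis) in each of 3 treated and 3 control mice, circles, with lines at the group means, in dermal γδ T cells and CD4 T cells of the imiquimod experiment and dermal γδ T cells of the oxazolone experiment. Il17a lies near 7834 against 564 CPM in the first panel and near 49.3 against 32.9 CPM in the last.

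Type 17 transcripts were also counted in other classes of the imiquimod mice. In CD4 T cells Il17f rose by 3.22 ± 0.42, and Il22 stood at 3625 ± 1631 against 444 ± 677 CPM and was not called (adjusted p = 0.447). The Il22 change was 3.16 on the log2 scale and ran from 2.545 to 6.064 over the alternatives. In dendritic epidermal T cells Il17a rose by 4.10 ± 0.23, from 3.94 ± 1.66 to 67.6 ± 2.1 CPM, and Il17f by 2.56 ± 0.20. In the latter class the 3 treated mice had 2.37, 3.72 and 3.15 Il22 UMIs per Il17a UMI, beside 2.37, 4.44 and 3.12 in dermal γδ T cells of the same mice. The same ratio was 2.37, 4.27 and 2.73 in monocytes or macrophages and 7.16, 59.9 and 34.5 in CD4 T cells. In ILC2, Il17a stood at 269 ± 180 against 4.52 ± 2.82 CPM and was not called (adjusted p = 0.0641). It was called with DESeq2 (5.93), with the 20% mitochondrial limit (4.37), at Leiden resolution 0.8 (4.10) and without IMQ 2 (6.39). The markers of dermal γδ T cells leave room for all counts of Il17f in CD4 T cells, of Il17a and Il17f in dendritic epidermal T cells and of Il17a and Il22 in ILC2 to be their transcripts (bounds of 196, 207, 342, 382 and 199.7%).

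**Figure D3:**
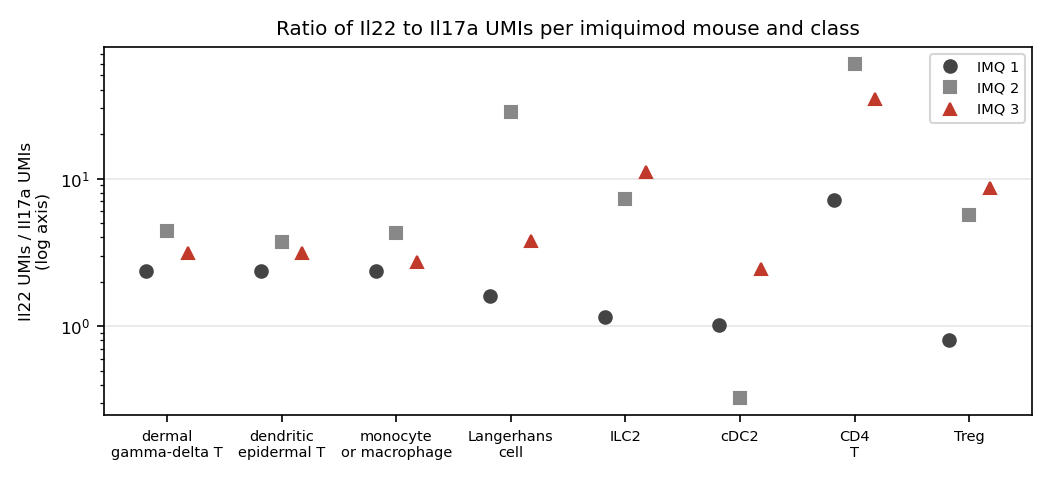
Ratio of Il22 to Il17a UMIs (log axis) in each imiquimod mouse, symbols, by cell class. Dendritic epidermal T cells and monocytes or macrophages lie near the ratios of dermal γδ T cells, and CD4 T cells lie above them in all 3 mice.

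Interferon-stimulated genes rose in all 9 classes tested. All 34 measured members rose in monocytes or macrophages and all 33 in cDC2. So did 25 of 26 in ILC2, 18 of 20 in dendritic epidermal T cells, 17 of 20 in CD4 T cells, 17 of 19 in Langerhans cells, 16 of 19 in dermal γδ T cells, 15 of 17 in Treg and 12 of 17 in cycling cells. Adjusted over the list alone, the counts were 34, 33, 26, 20, 20, 18, 17, 17 and 14 in the same order. Of the genes called upward in every class, Rtp4, a chaperone of taste and opioid receptors, rose on average by 3.48 over the 9 classes, Zbp1, a sensor of nucleic acids, by 3.33 and Xaf1 by 2.80. Isg20, an exonuclease, rose by 2.75, Irf7, the transcription factor that amplifies interferon production, by 2.57 and Isg15, a ubiquitin-like modifier, by 2.38. MHC class I presentation genes rose as a list in all 9 classes too, with 16 of 18 members called upward in monocytes or macrophages (17 adjusted over the list alone) and the peptide transporter Tap1 higher by 2.13 on average. Ly6a, AW112010 and Trim30a rose in every class by 2.71, 2.63 and 1.89 on average. With an estimated correlation, adjusted p ran from 0.0859 to 0.159 for the interferon list and from 0.0958 to 0.204 for the class I list.

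In monocytes or macrophages after imiquimod, Lcn2, an iron-sequestering antimicrobial protein (chromosome 2, 32384637 to 32387739), stood at 151 ± 49 CPM against 0.851 ± 0.743, from 1677 and 2 UMIs. Saa3, an acute-phase protein, rose by 5.73 ± 0.88, Cd300e, a receptor of monocytes, by 4.46 ± 0.46 and Il1b by 1.65 ± 0.11, from 1229 ± 114 to 3844 ± 340 CPM. Genes of resident tissue macrophages fell: 12 of 19 members of that list (13 adjusted over the list alone), among them the haemoglobin scavenger receptor Cd163 by 3.39 ± 0.31, the carbonyl reductase Cbr2 by 2.45 ± 0.20 and the chemokine Ccl24 by 2.97 ± 0.65 (fry adjusted p = 0.00289; adjusted p = 0.0891 with an estimated correlation). Pf4 fell by 3.53 ± 0.52 and Pmp22 by 2.03 ± 0.43. S100a8, an alarmin of neutrophils, stood at 574 ± 482 against 30.1 ± 27.6 CPM and was not called (adjusted p = 0.0589), while DESeq2 called it (adjusted p = 0.00762), as did edgeR with doublets kept (0.0436) and at Leiden resolution 0.8 (0.0411). Of the mitochondrial transcripts, 4 of 13 fell in this class. Treated cells of the class lay mainly in clusters 19, 20, 25 and 26 and control cells in clusters 28 and 36. With up to 20% mitochondrial UMIs admitted, the class changed members and 212 genes were called instead of 2420, Saa3 and Pf4 no longer among them (adjusted p = 0.102 and 0.0529), with Il1b higher by 0.53. At Leiden resolution 0.8 Il1b and Cbr2 stood at 1.03 and -1.41, and without the cells of highest doublet score Il1b stood at 0.86. Saa3 also lost its call without IMQ-C 2 (adjusted p = 0.066), Pf4 with the replicate number as a block (adjusted p = 0.0674) and Pmp22 without IMQ 2 or IMQ 3 (adjusted p = 0.059 and 0.0909).

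In cDC2, which present antigen to CD4 T cells, imiquimod raised 14 of 15 MHC class II presentation genes (15 adjusted over the list alone; fry adjusted p = 0.00587; adjusted p = 0.159 with an estimated correlation). They included H2-DMb2, part of the peptide exchange factor H2-DM, by 1.40 ± 0.16, the costimulator Cd86 by 1.16 ± 0.14 and the protease Ctss by 0.85 ± 0.10. The interferon-induced genes Phf11b, Ifit3 and Phf11d rose by 5.30 ± 0.27, 5.19 ± 0.60 and 4.92 ± 0.33. Il1b rose by 1.00 ± 0.17, and Nrip3 and Spry2, an inhibitor of growth factor signalling, fell by 3.09 ± 0.28 and 2.53 ± 0.25. In Langerhans cells, the DC of the epidermis, H2-DMb2 rose by 1.36 ± 0.11, Ifitm3 by 3.52 ± 0.55, Irf7 by 2.89 ± 0.65 and Il1b by 0.85 ± 0.20, and Mest and Atp1b1 fell by 1.96 ± 0.19 and 1.84 ± 0.22. In these cells 5 of 13 class II genes rose (7 adjusted over the list alone; fry adjusted p = 0.0254; adjusted p = 0.276 with an estimated correlation). With the 20% mitochondrial limit Ctss in cDC2 was not called (0.25, adjusted p = 0.199), and H2-DMb2, Cd86 and Il1b there stood at 0.74, 0.57 and 0.58. Leaving out IMQ 1 ended the call of Il1b in cDC2 (adjusted p = 0.0671) and leaving out IMQ 1, IMQ 2 or IMQ 3 that of Il1b in Langerhans cells (adjusted p = 0.135, 0.0834 and 0.0694) and of Irf7 there (adjusted p = 0.12, 0.132 and 0.114). Leaving out IMQ-C 1 or IMQ-C 3 ended those of Irf7 (adjusted p = 0.152 and 0.0661) and Ifitm3 (adjusted p = 0.0789 and 0.0541) in Langerhans cells. Without the cells of highest doublet score, Ifitm3, Atp1b1 and H2-DMb2 there stood at 5.52, -1.21 and 0.72. Of the cDC2, 203 of 343 treated and 92 of 737 control cells lay in cluster 24, and 297, 248 and 100 control cells in clusters 22, 23 and 32. Of the Langerhans cells, 98 of 151 treated and 91 of 290 control cells lay in cluster 29. Trdc, a marker of dendritic epidermal T cells, stood at 971 CPM in control cDC2 and 1176 CPM in control Langerhans cells, against 6267 CPM in control dendritic epidermal T cells, whose share fell. At these levels up to 57.7 and 60.4% of the Nrip3 and Spry2 counts of control cDC2 and 80.2 and 74.6% of the Mest and Atp1b1 counts of control Langerhans cells may be transcripts of those T cells, so these 4 falls may not be changes of the DC.

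In ILC2, which make type 2 cytokines, Ifit1, Rtp4 and Ms4a4b rose by 5.32 ± 0.30, 4.69 ± 0.26 and 4.40 ± 0.35. Areg, an epidermal growth factor receptor ligand, rose by 1.44 ± 0.13 and the type 2 cytokine Il13 by 1.10 ± 0.13, and 3 of 6 members of the type 2 list rose (3 higher and 1 lower adjusted over the list alone; fry adjusted p = 0.0148; adjusted p = 0.114 with an estimated correlation). Xlr4a and Map1b fell by 0.98 ± 0.20 and 0.93 ± 0.19. Cluster 16, led by Cxcl10, Ifit1 and Ms4a4b, held 116 of 589 treated and 12 of 1059 control ILC2. In CD4 T cells Ifitm3 rose by 3.89 ± 0.52, Zbp1 by 3.19 ± 0.29 and the inhibitory receptor Ctla4 by 2.62 ± 0.32, while Mest fell by 2.54 ± 0.39 and Amd1 by 1.02 ± 0.22 (DESeq2 adjusted p = 0.0932). Ifitm3 there lost its call without IMQ-C 2 or IMQ 1 (adjusted p = 0.134 and 0.0574). Treg raised Ifit1 by 4.32 ± 0.52, Iigp1 by 3.28 ± 0.42, Zbp1 by 3.26 ± 0.32 and Ctla4 by 0.90 ± 0.17, and lowered Anxa1 by 1.66 ± 0.27. Foxp3, the transcription factor that defines them, stood at a change of -0.09 ± 0.17 (adjusted p = 0.856) and Il10 at -0.28 ± 0.35 (adjusted p = 0.771; -1.03 and called without IMQ 2). Dendritic epidermal T cells raised Ifi27l2a by 4.27 ± 0.29, Ifitm3 by 3.85 ± 0.16 and Ly6a by 2.61 ± 0.32, and lowered Nrip3 by 0.86 ± 0.10 and Hspa2 by 0.84 ± 0.11. Ly6a lost its call with the replicate number as a block, and without IMQ-C 1, IMQ-C 2, IMQ 2 or IMQ 3 (adjusted p = 0.0728, 0.0701, 0.0753 and 0.105). Cluster 2 held 534 of the 937 treated and 805 of the 4044 control cells of this class. Dermal γδ T cells raised Ifi27l2a by 4.44 ± 0.43 and Ifitm3 by 3.71 ± 0.26. By the markers of the other class, up to 82.3% of the Mest counts of control CD4 T cells may be transcripts of dendritic epidermal T cells. In treated cells this bound was 69.0 and 64.6% for Ifitm3 in dermal γδ and dendritic epidermal T cells (monocytes or macrophages) and 57.8% for Ifi27l2a in the latter (CD4 T cells).

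Summed over the 9 classes, imiquimod changed 9726 gene-by-class results, 5378 higher and 4348 lower. The most were in monocytes or macrophages (2420 of 8570 genes), cDC2 (2268 of 7440) and dermal γδ T cells (1734 of 7224), and the fewest in Treg (133 of 2576) and CD4 T cells (170 of 4854). In at least 3 classes the same way, 1244 genes were called (676 higher, 568 lower), and 22 in all 9, of which the splicing factor gene Srsf3 alone fell. Of 142 tests of gene lists, 68 passed fry (62 upward), which asks whether the members changed. None passed camera with an estimated correlation, which sets them against the other genes (lowest adjusted p = 0.0859, 43 at an unadjusted p under 0.05). Glycolysis and hypoxia genes rose as a list in 8 of 9 classes, alarmins, type 17 genes and NF-kB targets with inflammatory cytokines in 6 each, regulatory and checkpoint genes and skin homing genes in 4 each. Lists also rose for type 1 and cytotoxic genes in 3 with a fall in 1, type 2 genes in 2 with a fall in 1, class II genes in 2, and cell cycle genes in 1, the cycling cells. Eicosanoid genes rose in 2 of 3 classes, tissue macrophage genes fell in 2 of 6, and dissociation stress and mitochondrial transcripts fell in 1 of 9 each. The list of keratinocyte transcripts, a sign of free RNA, passed in none of 7 classes and monocyte-attracting chemokines in none of 2; transcripts of fibroblasts and red cells had too few measured members.

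The third question was what the oxazolone challenge changed within classes of already sensitised mice. The human cells of these libraries, whose source, handling and exposure the labels do not describe, also differed between OXA and OXA-C libraries: 9250 of 15735 human genes were called, 4775 higher and 4475 lower. Each oxazolone change below may therefore hold a part that belongs to the libraries. For genes with a same-named human gene, the change was also computed relative to the human cells. Of the 28 named gene-by-class results that could be plotted that way all 28 kept their direction and 26 their call, the exceptions being Cd74 in cDC1 (-0.93, adjusted p = 0.0544) and Nme2 in dermal γδ T cells (-0.94, adjusted p = 0.0719). These 28 were chosen for large changes. Over all genes with a human counterpart, 19156 gene-by-class results were called in the mouse cells alone, and 9919 of them were also called in the same direction relative to the human cells. By class this ran from 223 of 874 in ILC2 to 3566 of 5229 in monocytes or macrophages. Each relative change also carries the error of the human change, so a lost call does not show that the change belongs to the libraries.

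**Figure D4:**
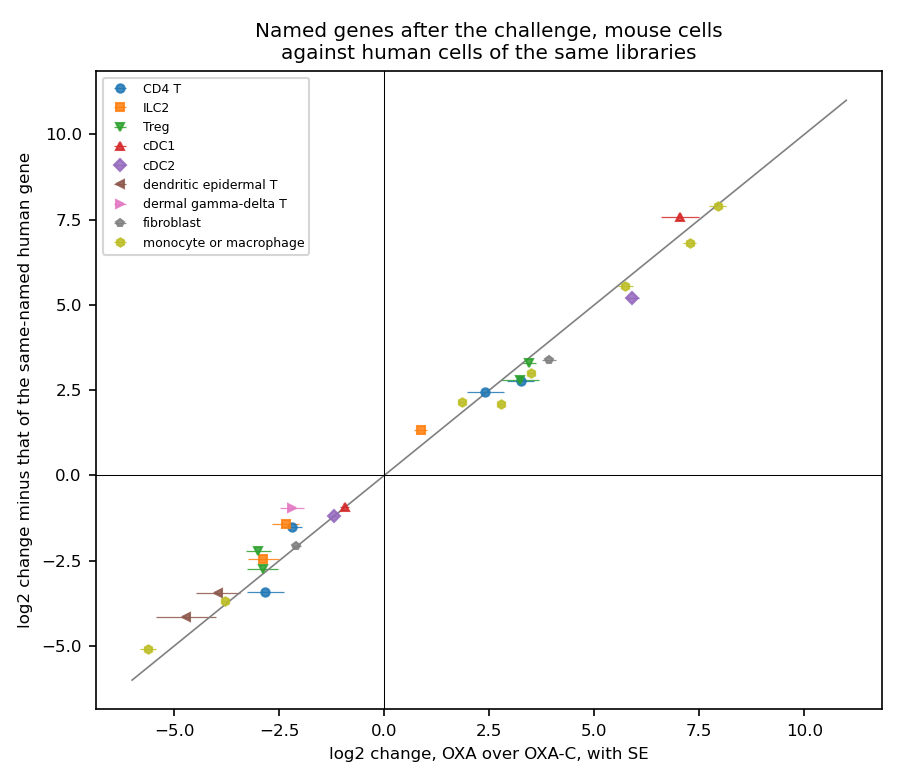
Log2 change after the challenge (OXA over OXA-C, bars show SE) of named genes, symbols by mouse cell class, against the same change minus that of the same-named human gene in the human cells of these libraries; the grey line marks equal values. All 28 results keep their direction.

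Monocytes or macrophages showed the largest number of changes. Arg1, the arginine-degrading enzyme (chromosome 10, 24915207 to 24927470), stood at 750 ± 92 CPM after the challenge against 0.103 ± 0.179 in controls (SD, n = 3 each), from 18557 and 1 UMIs. Inhba, a subunit of activin A, rose by 7.94 ± 0.20 and Nrg1, a growth factor, by 7.27 ± 0.16. Genes of glycolysis and hypoxia rose in 16 of 18 cases (16 adjusted over the list alone): the hypoxia factor Hif1a by 2.78 ± 0.08, from 75.0 ± 4.4 to 518 ± 2 CPM, the angiogenic factor Vegfa (chromosome 17, 46016993 to 46032377) by 5.74 ± 0.17 and the glycolytic enzyme Pkm by 1.84 ± 0.08 (fry adjusted p = 0.000594; adjusted p = 0.163 with an estimated correlation). Relative to the human cells these 3 rose by 2.11, 5.57 and 2.15. Also higher were Ptgs2, the inducible prostaglandin synthase, by 3.49 ± 0.09, Il1b by 2.21 ± 0.11, S100a8 by 5.39 ± 0.21, the chitinase-like Chil3 by 4.75 ± 0.12 and Cd274, encoding the checkpoint ligand PD-L1, by 3.71 ± 0.11. Tnf fell by 2.74 ± 0.08, from 523 ± 42 to 77.9 ± 5.3 CPM, and Il10 fell by 1.18 ± 0.11. Of 22 tissue macrophage genes, 15 fell and 7 rose, with the same counts adjusted over the list alone (fry adjusted p = 0.00113; adjusted p = 0.335 with an estimated correlation). Gas6, a ligand for clearing dead cells, fell by 3.78 ± 0.09 and F13a1 by 2.95 ± 0.08, and Cd209f stood at 0.131 ± 0.227 against 103 ± 24 CPM. The prostaglandin D synthase Hpgds fell by 4.34 ± 0.11, the leukotriene C4 synthase Ltc4s by 5.62 ± 0.19. Mucl1 fell by 8.16 ± 1.26 (-12.39, adjusted p = 0.0628, without OXA 2), and by the markers of cDC2 up to 59.5% of its counts in controls may be transcripts of cDC2. Interferon-stimulated genes rose in 30 of 33 cases (30 higher and 1 lower adjusted over the list alone; adjusted p = 0.174 with an estimated correlation). Treated cells lay mainly in clusters 20, 21, 22, 24, 26, 29, 30 and 35 and control cells in 25, 28 and 41. Cluster 21, led by Arg1, held 1703 treated and 0 control cells. The naming rules were adjusted after a cluster of Arg1-expressing macrophages had been left unnamed, and Arg1 without cluster 21 was not tested. Il1b stood at 1.11 with the 20% mitochondrial limit, 0.93 with doublets kept and 1.00 without the cells of highest doublet score, and Ptgs2 at 2.26 and 2.30 in the last 2 settings.

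In cDC2 after the challenge, the short-chain fatty acid receptor gene Ffar2 rose by 7.23 ± 0.18, Ifitm1 by 7.18 ± 0.12, B3gnt5 by 5.90 ± 0.15, the interleukin-4 receptor gene Il4ra by 2.44 ± 0.10 and Cd274 by 2.92 ± 0.12. Lyz1, which is nearly identical to its paralog Lyz2 and so uncertain, fell by 9.23 ± 0.24 and Tnf by 3.62 ± 0.18. Class II genes split, with 6 of 15 higher and 8 lower (the same adjusted over the list alone; fry adjusted p = 0.00589 downward; adjusted p = 0.594 with an estimated correlation); the invariant chain gene Cd74 fell by 1.20 ± 0.08 and H2-Eb1 by 0.89 ± 0.08. In cDC1, which cross-present antigen to CD8 T cells, Ifitm1 rose by 10.19 ± 0.26, Ifitm3 by 7.04 ± 0.44 and Plet1 by 7.03 ± 0.24, Cd274 stood at 104 ± 15 against 0.657 ± 1.139 CPM, and Clec4b1 at 1.31 ± 2.27 against 113 ± 11 CPM. Cd74 fell there by 0.94 ± 0.10 and Lyz1 by 5.61 ± 0.36 (-9.85 without OXA 1). The treated cDC2 lay mainly in cluster 27 and the control cDC2 in 23, 31, 32 and 40; for cDC1 these were clusters 39 and 36.

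Among lymphoid cells, Treg raised Satb1, a chromatin organiser, by 3.46 ± 0.17, Izumo1r, the folate receptor 4, by 4.50 ± 0.42, the inhibitory receptors Lag3 by 3.24 ± 0.45 and Ctla4 by 1.35 ± 0.14, and Foxp3 by 0.75 ± 0.14, while Anxa1 fell by 3.00 ± 0.29 and Pxdc1 by 2.89 ± 0.37. Of 17 regulatory and checkpoint genes, 12 rose and 3 fell in Treg (the same adjusted over the list alone; fry adjusted p = 0.00656; adjusted p = 0.203 with an estimated correlation). Of the dissociation stress genes 11 of 17 fell in Treg and 1 rose, and of the mitochondrial transcripts 8 of 13 fell (13 with 1 higher, and 11, adjusted over the list alone). Il10 fell in Treg by 0.55 ± 0.17 (adjusted p = 0.0138), but not with DESeq2 (adjusted p = 0.137) nor without OXA-C 2 or OXA 2 (adjusted p = 0.202 and 0.0879), and stood at 0.12 (adjusted p = 0.568) with the 20% mitochondrial limit. Gimap4, a GTPase of lymphocyte survival, stood at 138 ± 23 against 2.35 ± 4.08 CPM in Treg, and was higher in NK cells too. CD4 T cells raised the inhibitory receptors Havcr2 by 3.59 ± 0.34 and Ctla4 by 3.43 ± 0.32, Zeb2 by 3.26 ± 0.32 and Dusp4 by 2.41 ± 0.44, and lowered Hlf by 2.83 ± 0.44, Cebpb by 2.21 ± 0.24 and Ifng by 1.08 ± 0.21. In NK cells the granzyme gene Gzmc fell by 6.62 ± 0.78, from 5451 ± 2561 to 49.0 ± 48.2 CPM, and Ifng by 0.61 ± 0.19, a call that ended with DESeq2 (adjusted p = 0.197) and without OXA-C 3, OXA 1 or OXA 3 (adjusted p = 0.0875, 0.0778 and 0.0589). Treated and control NK cells lay in different clusters (11 and 17), as did Treg (6 and 8). With the 20% mitochondrial limit Foxp3 and Ctla4 in Treg stood at 1.29 and 2.08, Anxa1 there stood at -1.90 at Leiden resolution 0.8, and Cebpb in CD4 T cells at -3.41 after subtraction of free RNA. By the markers of ILC2, whose share fell, all Hlf counts and up to 55.4% of the Cebpb counts of control CD4 T cells, and all Pxdc1 counts of control Treg, may be transcripts of ILC2 (bounds for Hlf and Pxdc1 of 213 and 107%). Of the 151 named results of both experiments examined in this way, 18 reached 50%, each given here, and the highest of the others stood at 40.7%. The bound makes no allowance for sampling of sparse markers. For H2-Q6, Igtp and Il17a in challenged dermal γδ T cells it was 0, since the B cell marker Cd79a had no counts there. A low bound therefore does not exclude transcripts of other classes.

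ILC2 raised the paralogous inhibitory receptor genes Lilrb4a and Lilr4b by 4.17 ± 0.24 and 4.06 ± 0.22, Il1rl1, the interleukin-33 receptor, by 2.64 ± 0.25, Ly6c1 by 3.00 ± 0.33 and Areg by 0.86 ± 0.14 (0.49 without OXA 1, 1.34 relative to the human cells). Cd9 and Hist1h2bc fell in ILC2 by 2.88 ± 0.37 and 2.34 ± 0.32, the latter standing at -1.43 relative to the human cells, and Il13 stood at 0.39 ± 0.21 (adjusted p = 0.239; 0.62 and called without OXA 2). Dendritic epidermal T cells raised the guanylate-binding proteins Gbp2 and Gbp7 by 6.31 ± 0.85 and 3.89 ± 0.45 and H2-Q6 by 3.60 ± 0.38, while Mcrip2 and Pop4 stood at 3.26 ± 5.64 and 11.2 ± 19.5 CPM against 109 ± 10 and 187 ± 16. Cluster 16 held 98 of the 151 treated and 12 of the 1913 control cells of this class, and clusters 2 and 3 held 966 and 878 control cells. Dermal γδ T cells raised H2-Q6 by 3.15 ± 0.19 and the interferon-induced GTPase gene Igtp by 3.07 ± 0.36, and lowered Nme2 by 2.19 ± 0.29, Crip1 by 2.11 ± 0.14 and Tnf by 1.00 ± 0.27 (-1.70 without OXA 3). Their Il17a stood at a change of 0.62 ± 0.37 (adjusted p = 0.246; 49.3 ± 14.7 against 32.9 ± 3.1 CPM) and Il17f by -0.53 ± 0.52 (adjusted p = 0.556; -1.19 and called without OXA 2). Reads of H2-Q6 could not be told from those of other H2-Q genes with certainty, and the same holds for Lilrb4a and Lilr4b, Phf11b and Phf11d, Ifitm1 and Ifitm3, Amd1 and Amd2, and Gimap4 and its neighbours.

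Fibroblasts raised Cxcl5, a chemokine for neutrophils, by 7.75 ± 0.51, Chil1 by 6.13 ± 0.45, Dio2, which activates thyroid hormone, by 5.94 ± 0.52, Ptgs2 by 3.92 ± 0.17 and the alarmin cytokine Il33 by 3.34 ± 0.56. The collagen genes Col1a1 and Col1a2 fell by 2.10 ± 0.11 and 1.79 ± 0.11, Dlk1 by 3.79 ± 0.28 and Angptl7 by 3.48 ± 0.20. In fibroblasts, 10 of 18 NF-kB targets and inflammatory cytokines rose and 3 fell (the same adjusted over the list alone; fry adjusted p = 0.00324; adjusted p = 0.163 with an estimated correlation), and 13 of 18 glycolysis and hypoxia genes rose (13; adjusted p = 0.151 with an estimated correlation). Il33 stood at 7.99 among cells of matched depth and Angptl7 at -8.33 at Leiden resolution 0.8.

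Summed over 11 classes, the challenge changed 22800 gene-by-class results, 11056 higher and 11744 lower, from 6258 of 10020 genes in monocytes or macrophages to 778 of 3373 in CD4 T cells. In at least 3 classes the same way, 2805 genes were called (1421 higher, 1384 lower). Among genes with a human counterpart these numbered 2401, and 1774 relative to the human cells. Of 52 genes called alike in all 11 classes 49 fell, among them Crip1 at -1.75 on average, Ier2 at -1.25 and Capg at -1.20. Of 156 list tests 90 passed fry (52 upward), and none passed camera with an estimated correlation, which sets the members against the other genes (lowest adjusted p = 0.151, 34 at an unadjusted p under 0.05). Upward calls came for class I genes in 9 of 11 classes, interferon-stimulated genes in 8 of 11, glycolysis in 7 with a fall in 1, regulatory genes in 8 of 10 with a fall in 1, and type 2 genes in 5 of 7. They also came for type 1 genes in 4 of 10, type 17 genes in 3 of 8 and skin homing genes in 3 of 11. NF-kB targets and inflammatory cytokines rose in 3 classes and fell in 3, eicosanoid genes rose in 1 and fell in 1 of 3, and alarmins rose in 1 and fell in 6 of 8. Class II genes fell in 3 of 8, tissue macrophage genes in 2 of 5, cell cycle genes in 2 of 10 and monocyte-attracting chemokines in 1 of 4. The type 2 list in cDC2 and the skin homing list in fibroblasts passed upward with medians of -0.67 and -0.81, and the eicosanoid list in monocytes or macrophages passed downward with a median of 0.15. Dissociation stress genes and mitochondrial transcripts fell in 7 of 11 classes each, transcripts of fibroblasts in 3 of 4 and of keratinocytes in 1 of 2 classes; red cell transcripts could not be tested. In the human cells the same-named alarmins stood at a median of -0.70 and glycolysis genes at -0.31, and mitochondrial transcripts at -0.000776.

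A further question was whether the 2 responses differ within a class. The test of the imiquimod change minus the oxazolone change called 11800 gene-by-class results over 8 shared classes, 6879 of them more positive after imiquimod, and the experiments also differ in kit, digestion enzyme and mouse age. With RLE scaling 6200 of 11606 were more positive, so this split depends on the scaling. With TMM the median difference of all genes was 0.172 in ILC2, 0.150 in dendritic epidermal T cells and 0.138 in dermal γδ T cells. In monocytes or macrophages the transcription factor Runx3 had log2 changes of -0.36 after imiquimod and 4.41 after oxazolone, a difference of -4.74 ± 0.19. Hpgds had -0.46 and -4.34 (3.91 ± 0.23) and Clec4b1, a C-type lectin, 1.34 and -2.49 (3.85 ± 0.22). In cDC2 the apolipoprotein gene Apod had 1.12 and -3.91 (5.00 ± 0.20) and the prion protein gene Prnp 0.54 and 5.05 (-4.52 ± 0.26). In ILC2 Hif1a had 0.28 and 2.15 (-1.83 ± 0.19) and in Treg Satb1 1.24 and 3.46 (-2.25 ± 0.35). In dermal γδ T cells the galectin gene Lgals1 had 0.65 and -1.54 (2.28 ± 0.16). There the changes of Il17a (3.27 ± 0.82, adjusted p = 0.0236) and Il17f (3.49 ± 0.70, adjusted p = 0.00811) were more positive after imiquimod. These 2 genes were tested after their values were seen, and Il17a lost its call without OXA 1, OXA 2 or OXA 3 (adjusted p = 0.0815, 0.0643 and 0.065) and with the replicate number as a block. Relative to the human cells 5946 results were called, against 10041 for the same genes without that step, Ubb in Treg lost its call (0.57, adjusted p = 0.232) and Hif1a in ILC2 stood at -1.15. That fit took the mouse and human sums of an oxazolone library as independent. The fit of the oxazolone change alone paired them by library.

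Surface proteins were compared on the 42 antibodies between OXA and OXA-C mice. In NK cells the integrin CD103, a marker of tissue residence, fell by 5.95 ± 0.67 (adjusted p = 0.00352) and CD44 by 4.18 ± 0.53 (adjusted p = 0.00376), and CD64 fell by 3.08 ± 0.62. Of these cells, 285 of 288 treated ones lay in cluster 11, with an NK score of 4.025. In cluster 17 lay 87 of 94 control ones, with a score of 0.873 beside 0.691 for dendritic epidermal T cells. The falls may therefore be a difference between cell populations. In cDC1 CD274 rose by 2.15 ± 0.39 (adjusted p = 0.0281), CD11b by 1.52 ± 0.37 and CD21-CD35 by 1.11 ± 0.20, and CD24 and CD192 fell by 1.78 ± 0.43 and 1.21 ± 0.29. The MHC class II antibody I-A-I-E fell in cDC2 by 1.48 ± 0.28 (adjusted p = 0.0338). Treg raised CD62L, a lymph node homing receptor, by 1.74 ± 0.35 and CD8a by 2.02 ± 0.42, and dendritic epidermal T cells raised CD8a by 1.15 ± 0.25 and lowered KLRG1 and CD192 by 1.01 ± 0.26 and 1.24 ± 0.29. CD8a stood at 0.733 against 0.181% of the scaled antibody counts in Treg and at 0.332 against 0.150% in dendritic epidermal T cells. The share of CD8 T cells rose too, and how far free antibody or doublets hold the antibody counts of a class was not tested. These 14 calls came from 462 tests (89 at an unadjusted p under 0.05), and 6 of 11 classes had none. No isotype control was among the antibodies, and OXA-C 2 had a median of 153 antibody counts per mouse cell beside 126 per human barcode. The number of calls ranged from 5 to 56 when 1 library was left out, at 30, 56 and 26 without OXA-C 1, 2 and 3 and 8, 5 and 10 without OXA 1, 2 and 3. In cDC1 it fell from 5 to 0 without OXA-C 1, OXA 1 or OXA 2 and to 1 without OXA-C 3 or OXA 3. In dendritic epidermal T cells it fell from 3 to 0 without OXA 1 or OXA 2 and to 1 without OXA 3. In Treg it fell from 2 to 0 without OXA 1 or OXA 2, in cDC2 from 1 to 0 without OXA 2 or OXA 3 and in NK cells from 3 to 2 without OXA-C 1 or OXA 2. The replicate number as a block left 0 calls in NK cells, cDC1 and dendritic epidermal T cells, 1 each in cDC2 and ILC2 and 7 in Treg. Without the cells of high antibody totals there were 6 in NK cells, 3 in Treg, 2 in cDC1 and 0 in dendritic epidermal T cells. With limma on centred log-ratios 5 were called, 3 in NK cells and 2 in Treg, and the cDC1 changes stood at an adjusted p of 0.0845, I-A-I-E at 0.129, those of dendritic epidermal T cells at 0.223 and CD62L in Treg at 0.0895. Of 11 alternatives, CD103 in NK cells was called in 10, CD44 there in 9, and CD24 and CD192 in cDC1 and KLRG1 in 2 each. With total counts as library size, 61 were called, 58 of them higher, against 6 higher and 8 lower of 14. That setting moved the median antibody by 0.24 to 1.07 on the log2 scale, by class, so each change is relative to the other antibodies of its class.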

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

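The tests of resident shares and of the difference between share changes, and the choice of Il17a and Il17f for the test of the difference between responses, were made after the results were seen. The tests of library shift, free RNA and depth were chosen after the data were examined, but before their own results were seen.

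The human cells of the oxazolone libraries stand outside every mouse comparison, and 9250 of their genes differed between OXA and OXA-C libraries. The pattern weighed first is that of the 49 mouse genes lower in all 11 classes, 30 of which encode ribosomal proteins, with a median change of -0.81 for the 44 that have a same-named human gene. Free RNA and depth per cell are argued against as the whole cause: after subtraction of free RNA the median was -0.87 (-0.86 before, 11 classes), and among cells of matched depth -0.79 (-0.88 before, 8 classes). A shift of whole libraries fits, since all 44 human genes were lower too, with a median of -0.60, and the 53 human counterparts of genes higher in at least 9 classes stood at 0.54. Relative to the human cells, 5 of the 44 genes (NK cells) to 31 (cDC2) were still lower, and 8 turned higher in fibroblasts (7 lower) and 4 in cycling cells (6 lower), so a response of the mouse cells stays open for a part, and so does a difference in how the human cells were kept. Across genes, which are not independent replicates, the mouse and human changes had a Pearson r of 0.136 (monocytes or macrophages) to 0.501 (NK cells) and a Spearman rho of 0.214 to 0.592.

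The next pattern is the fall of the resident classes after the challenge, from 54.3 to 59.8% of the cells in OXA-C to 4.33 to 6.19% in OXA. Macrophages were not counted among these classes, since they were joined with monocytes. Their clusters 25, 28 and 41 held 1227, 882 and 82 control cells and 10, 4 and 3 treated cells. Whether the cells of these clusters were diluted, lost or changed was not tested. Entry of other cells alone may account for dendritic epidermal T cells, ILC2, fibroblasts, mast cells, dermal γδ T cells and Langerhans cells, whose changes among resident cells differed from each other by at most 1.45 standard errors, though this does not show that they changed alike. Keratinocytes and blood endothelial cells were set apart after the results were seen, so the agreement of the others was not a test of this cause. Entry alone cannot account for keratinocytes (-2.83 ± 0.44 among resident cells) and blood endothelial cells (1.73 ± 0.36), which differed by 8.07 standard errors, and 9 of 28 pairs of all these resident classes differed by more than 4. These standard errors were derived from the F value of each test. They were combined as if the classes were independent, though the classes share the same mice and total, so the distances are approximate. Barcodes lost at the cell filters were at most 15.2% of the missing resident cells, so they are too few. A difference in digestion or a true loss of these cells stays open as untested.

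A test of the difference called 11800 gene-by-class results between the imiquimod and oxazolone responses, and kit, enzyme and age stay open for all of them and the library shift for a part: of 10041 with a human counterpart, 4407 were called in the same direction relative to the human cells too. The fit relative to the human cells did not pair the mouse and human sums of a library here. Of the other splits drawn, 60 of 200 possible with the real one included, the highest called 8535. The splits relabel treated and control mice within each experiment, so they ask whether either treatment had an effect. They cannot decide whether the 2 responses differ beyond chance. By class, a count as large came in 3 of 60 splits in ILC2 (highest other 705, real 680) and in 5 in Treg (817 and 277). In each class the highest other split kept all 6 oxazolone libraries in their groups, so it still holds the oxazolone response. The Treg count, several times the real one, points to this structure of the samples. In dendritic epidermal T cells 2 splits called as many (913 and 858), and in each of the other 5 classes only the real one did. Since the splits cannot decide this question, they exclude chance in no class and show it in none. The named differences, imiquimod minus oxazolone, were in monocytes or macrophages 3.85 for Clec4b1, 3.23 for Pltp, 3.91 for Hpgds, -4.74 for Runx3 and -3.50 for Malt1. In cDC2 they were 5.00 for Apod, 4.97 for Slamf9, 3.77 for Clec4b1, -4.55 for Rhoq, -2.50 for P2ry10 and -4.52 for Prnp. In ILC2 they were 1.78 for S100a11, 1.46 for S100a6, -1.83 for Hif1a and -2.73 for Lilr4b, and in Treg 1.75 for Emp3, 1.55 for Ubb, -2.05 for Ighm and -2.25 for Satb1. In dermal γδ T cells they were 2.28 for Lgals1, 1.95 for S100a4, -2.05 for H2-Q4, -1.33 for Ifngr1, 3.27 for Il17a and 3.49 for Il17f. Relative to the human cells, Runx3 and Malt1 stood at -4.62 and -2.92, Apod, Rhoq and Prnp at 4.88, -4.12 and -4.13 and Satb1 at -2.08, while S100a11 and Hif1a in ILC2 stood at 1.14 and -1.15, Emp3 and Ubb in Treg at 1.08 and 0.57 (Ubb not called) and S100a4 in dermal γδ T cells at 1.15.

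Share changes differed between the experiments for 12 of 18 classes (edgeR). Blood endothelial cells (difference 4.08) and fibroblasts (4.73) moved in opposite directions, upward after imiquimod and downward after oxazolone, as shares of all kept cells. Among resident cells blood endothelial cells rose after oxazolone and fibroblasts stood at 0.13 ± 0.20, so the direction depends on which cells the share is taken of.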

How the results depend on the processing

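The alternatives of doublet score, free RNA, matched depth, antibody aggregates and the human cells were chosen after seeing the data. Of the results under other settings, 480 of class shares kept their call or lack of it, 26 lost the call, 1 gained it and 3 reversed (40 results). For named genes these were 2695, 49, 17 and 1 (176 results). Reversed means a change of sign with a call in either setting. A change of sign without a call in either was counted as kept. Counts per class stayed within 1.5 times in 497 cases and moved further in 96. The data do not show that the numbers of the mice pair them: same-numbered deviations correlated at 0.0269, 0.132 and -0.111 for imiquimod and -0.122, 0.0507 and -0.0891 for oxazolone, and not every mouse correlated best with its own number. So few correlations cannot exclude that a number marks a shared day or batch. With the replicate block, 9805 genes were called for imiquimod, 21609 for oxazolone and 11455 for the difference, 40 and 46 lists, and 9 antibodies; Il17a in dermal γδ T cells had an adjusted p of 0.069 for imiquimod and 0.127 for the difference, and Il17a in ILC2 0.000118 for imiquimod.

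For imiquimod, against 9726 genes, DESeq2 called 5985 and the 20% mitochondrial limit 6068, and leaving out a library gave 7358 to 9427. For oxazolone, against 22800, leaving out a library gave 18689 to 21204, and matched depth 13936 (19843 in the same classes). The difference between responses fell from 10041 to 5946 relative to the human cells. There each change also carries the error of the human change, and the mouse and human sums of a library were not paired. For the difference, leaving out a library gave 9619 to 11536. RLE moved the median gene by at most 0.12, in ILC2. Genes shared between classes numbered 765 with DESeq2, 2294 over 2 classes and 701 over 4 for imiquimod (1244), and 1854, 5131 and 1679 for oxazolone (2805). With camera 0 lists passed in both experiments, and leaving out a library gave 42 to 54 (45, 42 and 44 without IMQ-C 1, 2 and 3) against 68 and 67 to 80 against 90. Antibody calls numbered 5 with limma on centred log-ratios, 61 with total counts and 5 to 56 when a library was left out. Reversed were the cDC2 share after imiquimod (0.0438 with the 20% limit and 1.37 at Leiden 0.8, against -0.65), the plasmacytoid DC share after oxazolone (-2.68 at Leiden 0.8, against 4.09) and Il10 in Treg after oxazolone (0.12 with the 20% limit, against -0.55). The causes of these moves were not tested. Of the 3 oxazolone classes simulated, ILC2 had the lowest share of changes of 1 called (27.1%).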

Other observations

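The tests of Il22 and Il17a were chosen after the result was seen; the splits of the libraries were planned.

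Genes of MHC class I presentation rose in the resident lymphocytes after the oxazolone challenge. They numbered 15 of 18 in dermal γδ T cells with 1 lower (the same adjusted over the list alone), 11 of 18 in dendritic epidermal T cells (14) and 9 of 18 in ILC2 (11), each with an adjusted p of 0.151 with an estimated correlation. Interferon-stimulated genes rose in 12 of 18, 7 of 11 and 8 of 13 cases in the same order, with 1 lower in dermal γδ T cells (12, 7 and 9 higher adjusted over the list alone; adjusted p = 0.163, 0.181 and 0.258 with an estimated correlation). Dissociation stress genes fell in 12 of 17 cases in dendritic epidermal T cells with 1 higher (13 and 1 adjusted over the list alone), in 5 of 17 in ILC2 with 2 higher (6 and 5) and in 3 of 17 in dermal γδ T cells with 4 higher (4 and 5). Mitochondrial transcripts fell in 9, 8 and 8 of 13 cases in them (10, 11 and 11 adjusted over the list alone; adjusted p = 0.163, 0.218 and 0.163 with an estimated correlation). Alarmin genes fell in 4 of 6, 4 of 5 and 4 of 5 cases, with the same counts adjusted over the list alone (adjusted p = 0.203, 0.163 and 0.151 with an estimated correlation), and the same-named human genes were lower in 4 of 4 cases. In NK cells 10 of 14 type 1 and cytotoxic genes rose and 2 fell (the same adjusted over the list alone; adjusted p = 0.229 with an estimated correlation). There 285 of 288 treated cells lay in cluster 11 and 87 of 94 control cells in cluster 17, so a difference between cell populations stays open.

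Cycling cells, which mix lineages, raised 14 of 17 class I genes and 10 of 17 glycolysis and hypoxia genes after imiquimod, with 1 of the latter lower (16, and 11 higher with 1 lower, adjusted over the list alone; adjusted p = 0.0958 and 0.114 with an estimated correlation). After oxazolone they raised 11 of 14 regulatory and checkpoint genes (13; adjusted p = 0.163 with an estimated correlation) and lowered 6 of 10 class II genes (7; adjusted p = 0.229 with an estimated correlation), and dissociation stress genes were lower in 10 of 17 cases. The mix differed between groups: after oxazolone cluster 37, whose markers score highest for cDC2, held 17 of 124 treated and 169 of 380 control cells, and cluster 12, which scores highest for CD4 T cells, 99 and 183. After imiquimod cluster 13 held 117 of 156 treated and 164 of 336 control cells. A change in the mix therefore stays open for these lists.

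Il22 and Il17a were counted in several classes of imiquimod mice, at 95.4, 129 and 152 Il22 UMIs per dermal γδ T cell and 6.37, 15.2 and 19.8 per CD4 T cell. In dendritic epidermal T cells and monocytes or macrophages, free RNA of dermal γδ T cells is a candidate source, since the ratio of Il22 to Il17a over that of dermal γδ T cells lay at 0.839 where farthest from 1. Doublets are argued against there as the main source, since over the 3 mice 100% and 85.1% (76.1, 100 and 84.8% by mouse) of the summed Il22, Il17a and Il17f UMIs lay in cells with fewer of them than the median dermal γδ T cell of the same mouse. In CD4 T cells 11.7% did, and relative ratios of at least 3.02 argue against free RNA, while the ratio in the 12, 8 and 9 remaining cells of the 3 mice argues against doublets, since at most a share of 0.0442 of 10000 draws of as many dermal γδ T cells lay as far (two-sided), so expression of Il22 by cells of this class is a hypothesis. The class joins cluster 11 (156 of 282 treated cells), with Cd4 among its 10 leading genes, and cluster 9 (126), led by Cd40lg and Zbtb16 without Cd4. Which of these clusters holds the Il22 UMIs was not examined. In Langerhans cells and ILC2 free RNA is argued against as the only source, since at most 57.7% of the UMIs of a mouse lay in cells below that median, and doublets are a candidate source (at most 21.3% below it over the 3 mice), as is expression by a few cells, while in cDC2, with 1, 1 and 0 cells at or above it, neither a relative ratio as far as 0.0732 nor the 48.4% below it decides.

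Each experiment's 6 libraries make 10 splits, too few for a share under 0.05. The real split and the highest other called 9726 and 6 genes, 1244 and 0 shared genes, 68 and 0 lists and 13 and 0 class shares for imiquimod, and 22800 and 1, 2805 and 0, 90 and 0 and 20 and 0 for oxazolone. For antibodies they called 14 and 12. By class these were 2 and 8 in Treg, 3 and 3 in dendritic epidermal T cells, 3 and 0 in NK cells, 5 and 0 in cDC1 and 1 and 0 in cDC2. The split with 8 in Treg, several times the real count, set OXA-C 2, OXA 1 and OXA 2 against the others and points to a structure of the samples.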
